A study of Danio rerio with 4 samples.

How the data were processed

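Hearts with surrounding tissue were drawn from zebrafish embryos at 48 hours post fertilization by syringe, total RNA was isolated and labelled with biotin, per the labels' protocols, and hybridised to Affymetrix Zebrafish arrays. Embryos were kept in vials of 3 mL with up to 20 embryos each in 10 μM SU5402, diluted from a 1 mM stock, or in 1% DMSO. The 4 arrays fall into 2 groups of 2 by their treatment labels, and replicate numbers come from the same labels. All 4 columns of the value table belong to these arrays, and 0 other columns were present.

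The deposited values are probe set intensities on a linear scale, 1 per probe set and array. The algorithm that summarised the probes, the software and the scaling are not given in the sources used here. From the values, the mean after trimming 2% at each end was 500.1 on every array, medians were 184.4 and 179.3 (DMSO) and 177.3 and 172.9 (SU5402), and the distributions differed, so each array was scaled to a common trimmed mean and not quantile normalised. Detection calls and scanner files were not used here, and no depth exists for arrays. As a measure of signal over background, the 17 Tag control probe sets, which have no target in zebrafish RNA, had a 95th percentile of 136 in intensity (log2 7.25), and 56.1% and 56% of probe sets in the DMSO arrays and 56.1% and 55.2% in the SU5402 arrays lay above it. Gene names came from an old platform annotation updated through Entrez identifiers. Of 15502 probe sets tested, 10795 had 1 symbol, 135 several and 4572 none, and 10711 of the first were matched to a current gene. The 115 control probe sets were left out of the tests.

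Intensities were taken to log2(value + 16) without further normalisation or filtering and fitted with limma (lmFit and eBayes, version 3.58.1, R 4.3.3) with treatment as the single term and Benjamini-Hochberg adjustment over all probe sets, at a threshold of 0.05. All tests were two-sided. A gene was represented by its probe set with the highest mean over the 4 arrays, which gave 8793 genes, 1539 of them with several probe sets. The test, its samples, the 29 gene lists of 662 symbols (418 measured, 21 entries matched through a synonym), the named genes' rule and most alternatives were fixed before the data were examined. Lists with at least 3 measured genes were tested with limma camera (preset inter-gene correlation 0.01, then an estimated correlation) and limma fry, with Benjamini-Hochberg adjustment over lists, and their members were also adjusted over the list alone. Intervals of list medians are 95% bootstrap intervals over genes (10000 resamples), and genes are not independent replicates.

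The genes named were the 12 with the largest rise and the 12 with the largest fall among those past the threshold with groups that did not overlap, filled up from those with an unadjusted p under 0.05 where too few passed; here none passed, and all 24 were filled in this way. Named as well were every measured FGF list member, cadm4, nkx2.5, vmhc (now myh7), myl7 and isl1 (isl1a), and up to 4 members with the lowest p of each list that passed and each list of another cell type. The rule also listed myh6 and ltbp3, for which no named probe set was used here. This gave 95 genes. Members that passed over their list alone in small counts, mybpc3, barx1, crabp2b and hey1, were named after their values were seen. So were cnmd, foxd3, fgf10a, fgf13a, fgfrl1a and the fin and reporter genes of the closing section. Of the 95, 15 had further probe sets, and 5 of these had one of opposite sign. On average 19 of the 95 lay below the Tag background in 1 group and a further 17 in both.

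The fit and set tests were tested on simulated data drawn with the spread of these arrays (15502 probe sets, 200 changed, 20 simulations). Each probe set was drawn independently of the others, so simulated lists held no correlation between genes. At the adjusted threshold 83.7%, 3.4% and 0.3% of probe sets changed by 4, 2 and 1 log2 units were recovered, with 2.7 false calls among 60.5 on average, and at an unadjusted p under 0.05, 99.8%, 94.8% and 58.6%. Alternatives planned beforehand were a replicate block, other variance models, filters on the dimmest 25% and 50% of probe sets, quantile normalisation, median centring, cyclic loess, pseudocounts of 1 and 64, each array left out, an adjusted p under 0.10, a 2-fold minimum, limma treat against 1.2-fold, the mean of a gene's probe sets and the other set tests. The count at an unadjusted p, the counts over each list alone in every setting, and a floor at the Tag background were added after the data were seen. The floor was first run with all probe sets kept, and a second form leaving out probe sets above it on no array was added after the first form's calls were seen; both are reported.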

Results

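Gene expression was measured in hearts and the tissue around them, taken from zebrafish embryos at 48 hours post fertilization. SU5402, a small molecule that blocks the kinase activity of fibroblast growth factor (FGF) receptors, was given at 10 μM, and siblings received 1% DMSO, its solvent. Each group had 2 replicates, each on 1 Affymetrix Zebrafish array of short oligonucleotide probe sets, so 4 arrays were compared. The start and length of the treatment are not given in the labels. The labels do not say whether the replicates came from separate clutches, and p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. With 1 array left out, 1 group is a single array and the spread comes from the other group's pair alone. P-values and counts from those settings are therefore not ordinary tests between groups. Across probe sets, the DMSO arrays correlated at r = 0.964 and the SU5402 arrays at 0.928, and pairs of arrays from different groups at 0.908 to 0.94; probe sets are not independent replicates. Changes are given as SU5402 minus DMSO on the log2(intensity + 16) scale, which understates the change of dim genes.

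The comparison of SU5402 with DMSO asked how transcripts of the heart region change under this inhibitor of FGF receptors. Whether SU5402 also acted through other targets was not tested. The most direct reading is in genes that FGF signalling induces. Of 16 listed FGF feedback and target genes, 11 were measured, and 8 of them were lower after SU5402, with a list median of -1.41 (95% bootstrap interval over genes -2.25 to 0.18) and a mean of -1.31. The ETS transcription factor gene etv5b fell from 11.16 ± 0.28 to 7.26 ± 0.07 (log2, SD, n = 2 each), a change of -3.90 (SE 0.32) or 14.9-fold, with an adjusted p of 2.29e-04 over the list alone in limma. Its relatives etv4 and etv5a fell by 2.42 and 2.25 (SE 0.38 and 0.45). The MAP kinase phosphatase gene dusp6 fell by 1.81 (SE 0.40), and the genes of the feedback inhibitors il17rd, spry4 and spred1 fell by 1.84, 1.41 and 0.95. These 7 genes passed limma at an adjusted p under 0.05 when adjusted over the list alone, and 0 of the 11 did so over all probe sets. The other 4 did not pass either adjustment, at -0.54 for dusp4, 0.30 for dusp5, 0.23 for dusp2 and 0.18 for spry2. With 1 array left out, dusp5 ran from 0.04 (without DMSO replicate 1) to 0.57 (without DMSO replicate 2), dusp2 from -0.75 (without SU5402 replicate 2) to 1.21 and dusp4 from -1.24 (without SU5402 replicate 2) to 0.15 (both highest without SU5402 replicate 1).

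The FGF list passed limma camera with its preset correlation (p = 2.84e-05, adjusted p = 2.75e-04 over 29 lists). This call was lost with an estimated correlation (limma camera, p = 0.236, adjusted p = 0.657), and limma fry gave p = 0.06 (adjusted p = 0.243). The estimated form also found 0 of 20 simulated lists shifted by 1 log2 unit, so its loss cannot decide for or against the list. Without DMSO replicate 2, 3 members passed over the list alone in place of 7, and 2 did with a floor, every value below the background of the Tag control probe sets raised to it, with all probe sets kept. A second form of the floor left out probe sets above it on no array, and there 6 of 9 members passed over the list alone (list median -1.41). In the SU5402 arrays, etv4 and il17rd lay on average below the 95th percentile of the Tag control probe sets (log2 7.25), so their falls are partly set by background, and etv5b lay at that level. Both dusp4 and spry2 lay below it in both groups, so neither was well above background on average. Other probe sets of spred1 and spry2 differed in sign from those used (highest 0.14 for spred1, lowest -1.09 for spry2). Second probe sets of etv5a and dusp6 fell by less than those used, at -0.46 and -1.01.

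**Figure D1:**
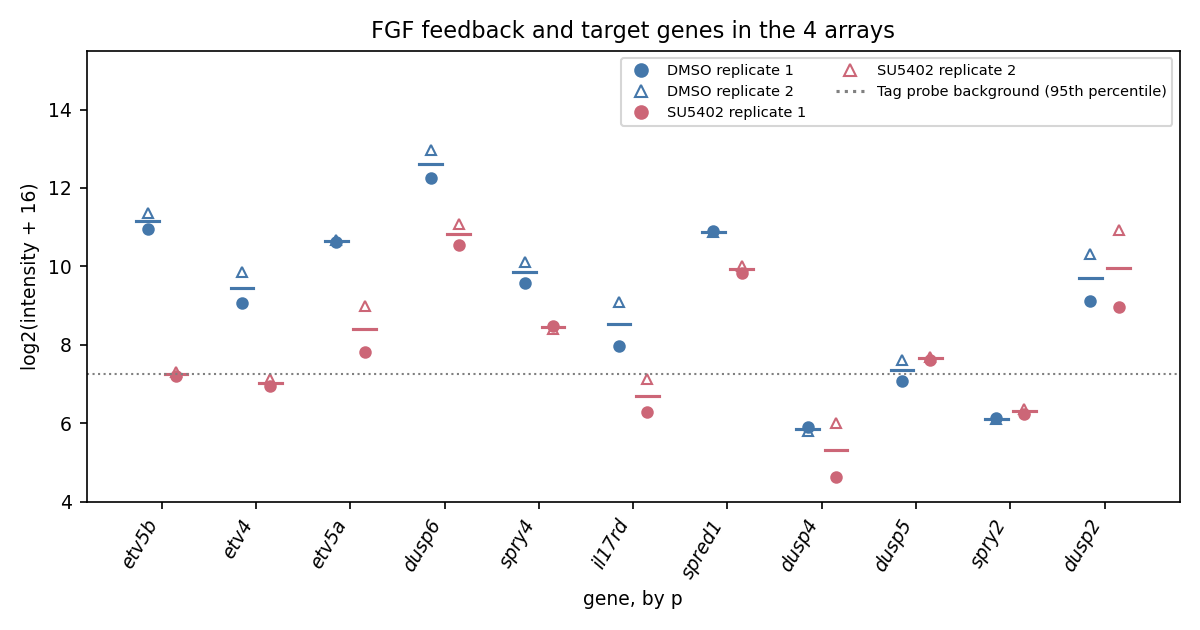
Log2(intensity + 16) of the 11 measured FGF feedback and target genes in each array, ordered by p; blue marks DMSO and red SU5402, circles replicate 1 and triangles replicate 2, short lines group means (n = 2), and the dotted line the Tag probe background. Both SU5402 arrays lie below both DMSO arrays for etv5b, etv4, etv5a, dusp6, spry4, il17rd and spred1.

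Over all genes, 0 of 15502 probe sets passed limma at an adjusted p under 0.05 (lowest 0.255), while 2008 had an unadjusted p under 0.05 where 775 would by chance, 1045 of them higher and 963 lower after SU5402. Without DMSO replicate 1 or 2, 955 and 951 probe sets had an unadjusted p under 0.05, and without SU5402 replicate 2, 3011 did and 3 passed the adjusted threshold. Both SU5402 arrays lay beyond both DMSO arrays for 44% of probe sets, against 33.3% by chance, and 1621 of these differed by at least 2-fold, 855 higher and 766 lower. A split into replicate 1 and replicate 2 arrays, whatever their treatment, gave 35.8% apart and 942 at 2-fold. The remaining split gave 20.3% and 328. A permutation of 2 against 2 arrays cannot give an exact p below 0.333. In simulated data of this design, limma recovered 83.7% of probe sets changed by 4 log2 units at the adjusted threshold, 3.4% of those changed by 2 and 0.3% of those changed by 1.

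The genes named next differed most among those with an unadjusted p under 0.05 and groups that did not overlap, and none passed the adjusted threshold. Below DMSO were the actinodin genes and2, and3 and and1 (-5.12, -4.63 and -3.97; SE 0.99, 1.37 and 0.97), which encode structural proteins of the fin fold. Genes of mesenchymal transcription factors were prrx1b at -4.42 (SE 0.45) and tbx15 at -4.31 (SE 0.61). Also lower were angptl7 (-4.62, SE 0.55), the proteoglycan gene vcanb (-3.76, SE 0.37), fgfbp2a, whose family binds FGFs (-3.51), the retinoic acid binding protein gene crabp2a (-3.48, SE 0.57), the annexin gene anxa1b (-3.38) and si:ch211-76l23.4 (-3.37). Above DMSO, the complement gene c4b was at 3.42 (SE 0.40), the collagenase gene mmp13a at 3.28 (SE 0.77) and the gelatinase gene mmp9 at 3.04 (SE 0.99). The peptidase gene ace was at 2.61 (SE 0.31), the vesicular acetylcholine transporter gene slc18a3a at 2.51 (SE 0.44), and dmbx1a, a homeobox gene of the brain, at 2.27. Others were si:ch211-1a19.3 (2.99), spata20 (2.43), the fatty acid desaturase gene fads2 (2.21) and 3 cardiac muscle genes described next. Of these 24 genes, counting etv5b, 10 lay on average below the Tag background in 1 group, so their differences are partly set by background. Second probe sets of tbx15 and dmbx1a showed smaller differences, at -1.28 and 0.63. In and2, the SU5402 arrays themselves stood at 7.11 and 10.31 against 13.56 and 14.09 in DMSO, and and2 was at -6.72 and and3 at -6.9 without SU5402 replicate 2. Without SU5402 replicate 1, and2, and3 and and1 were at -3.52, -2.37 and -2.45. The values of mmp9 and mmp13a were 1.44 and 2.06 without SU5402 replicate 2 and 4.64 and 4.5 without SU5402 replicate 1.

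Of 29 gene lists fixed before the data were examined, 10 passed limma camera at an adjusted p under 0.05, 5 higher and 5 lower. With an estimated correlation 0 of the 10 calls held (limma camera, lowest adjusted p = 0.657), with 0 lists at an unadjusted p under 0.05, and limma fry, which asks whether a list's genes move one way on balance, called 1. In simulated data a list shifted by 1 log2 unit was found in 20 of 20 simulations with the preset correlation and in 0 with an estimated one. Simulated genes were drawn independently, while the estimated correlations of the 10 lists ran from -0.36 for the Cadm family to 0.87 for neurons. The simulation therefore cannot show which form of the test is right for these lists. It does show that the estimated form found 0 lists shifted by 1 log2 unit even without correlation between genes. Its loss of calls in this design therefore cannot decide for or against a list. No member of any list passed over all probe sets.

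Genes of heart muscle were higher after SU5402. Of 15 measured contractile genes, 13 were higher, with a list median of 1.19 (interval 0.14 to 1.84). The titin gene ttn.2 rose by 1.84 (SE 0.45), the cardiac actin gene actc1a by 1.25 (SE 0.37), the ventricular myosin heavy chain gene myh7 (also named vmhc) by 2.33 (SE 0.71), the troponin T gene tnnt2a by 2.32 (SE 0.71) and the myosin binding protein gene mybpc3 by 1.48, and the tropomyosin gene tpm4a fell by 1.15 (SE 0.30). These 5 higher and 1 lower passed limma adjusted over the list alone. Other probe sets of ttn.2 ran from 0.08 to 2.06. The myosin light chain gene myl7 did not, at 11.70 and 9.03 in the DMSO arrays and 13.17 and 12.20 in the SU5402 arrays. The list had an adjusted p of 4.74e-04 in limma camera (adjusted p = 0.657 with an estimated correlation). Its median differed by 0.69 between the DMSO arrays, and without DMSO replicate 2 the list median was 0.66 and 0 members passed over the list alone. The count was also 0 without SU5402 replicate 2, 1 higher without SU5402 replicate 1, and 8 higher and 1 lower without DMSO replicate 1. With a pseudocount of 1 or 64, or with values raised to the Tag background in either form, 0 members passed as higher over the list alone. Without DMSO replicate 2, myh7, tnnt2a, mybpc3 and myl7 were at 1.24, 1.36, 0.93 and 0.99, and myl7 was at 3.66 without DMSO replicate 1.

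Ventricular identity genes shared this direction, with 7 of 8 higher, a median of 0.84 (interval 0.31 to 1.78) and an adjusted p of 2.1e-03 in limma camera (adjusted p = 0.657 with an estimated correlation). The Iroquois genes irx4a, irx1a and irx5a were at 1.78 (SE 0.56), 1.2 (SE 0.46) and 0.70 (SE 0.32), and 0 members passed limma over the list alone, with 3 at an unadjusted p under 0.05. Without SU5402 replicate 1 the list was at 0.43 and its call was lost (limma camera, adjusted p = 0.0592), with irx4a at 1.02 and irx1a at 0.63. Without SU5402 replicate 2 it was at 1.31 with 3 members higher over the list alone, and without DMSO replicate 1, 1 member passed. Of 14 cardiac transcription factor genes, 10 were higher, with a median of 0.34 (interval -0.02 to 0.76). The GATA factor genes gata5 and gata6 were at 1.52 (SE 0.33) and 1.18 (SE 0.44), nkx2.5 at 1.06 (SE 0.39), isl1a at 0.76 (SE 0.41) and mef2ca at -0.90 (SE 0.47). 0 of them passed limma over the list alone, with 3 at an unadjusted p under 0.05. The list passed limma camera at an adjusted p of 0.0359 (adjusted p = 0.657 with an estimated correlation). That call was lost without DMSO replicate 1 (limma camera, 0.28, adjusted p = 0.0873) and without SU5402 replicate 1 (0.21, adjusted p = 0.165). Gene myh7 is in both the ventricular and the contractile list. Relative to each gene's mean, the ventricular median was 0.75 in SU5402 replicate 1 and 0.08 in SU5402 replicate 2. In the same arrays the contractile list was at 0.49 and 0.51, and the neuron list at 1.02 and -0.05. Whether the ventricular list rose in heart muscle or in the tissue around it was not tested. Without SU5402 replicate 1, gata6 and isl1a were at 0.66 and 0.32, without DMSO replicate 2 nkx2.5 was at 0.70, and without SU5402 replicate 2 mef2ca was at -0.28. Both nkx2.5 and mef2ca lay on average below the Tag background in both groups, and gata6 in the DMSO arrays.

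The 3 measured genes of the Cadm family of cell adhesion molecules rose, cadm2a by 1.40 (SE 0.30), cadm3 by 1.33 (SE 0.33) and cadm4 by 1.08 (SE 0.43), and all 3 passed limma over the list alone. The list had an adjusted p of 1.41e-03 in limma camera (adjusted p = 0.657 with an estimated correlation) and was the 1 list that limma fry called (adjusted p = 0.0146). This family was listed because cadm4 is known to have been followed up by the study, so its direction is not independent evidence. Without DMSO replicate 1, or without DMSO replicate 2, 0 members passed over the list alone, and without SU5402 replicate 2, 2 did, with cadm4 at 0.57. With a pseudocount of 1 or either form of the floor at the Tag background, 2 did. Neuronal genes rose as well, and whether the Cadm genes rose in heart or in the tissue around it was not tested. Relative to each gene's mean, the Cadm median was 0.72 and 0.68 in SU5402 replicates 1 and 2, and the neuron median 1.02 and -0.05.

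Cell cycle genes were lower after SU5402. Of 35 measured, 33 were lower, with a median of -0.98 (interval -1.13 to -0.80), and 15 fell when limma was adjusted over the list alone. The replication helicase genes mcm3, mcm5 and mcm2 fell by 1.87, 1.74 and 1.88 (SE 0.30, 0.31 and 0.34), and the ribonucleotide reductase gene rrm1 fell by 1.75 (SE 0.32). A second probe set of mcm3 was at 0.63. The list had the lowest adjusted p of the 29 in limma camera, 2.43e-11 (adjusted p = 0.657 with an estimated correlation). Without either DMSO array 0 members passed over the list alone, without SU5402 replicate 2, 5 did, and without SU5402 replicate 1, 25 did. With a pseudocount of 1, 5 passed, and with values raised to the Tag background and all probe sets kept, 1 did.

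Matrix genes and genes of neural crest and cartilage were lower. In the extracellular matrix list, 22 of 30 measured genes were lower (median -0.70, interval -0.94 to -0.41), and vcanb, the fibulin gene fbln1, the membrane-bound metalloproteinase gene mmp14b and the laminin gene lamb1a fell by 3.76, 2.28, 1.60 and 1.63, the 4 that passed limma over the list alone. A second probe set of fbln1 was at 0.44. This list passed limma camera (adjusted p = 5.99e-03, and adjusted p = 0.721 with an estimated correlation), and without SU5402 replicate 1 it was at -0.24 and the call was lost (adjusted p = 0.694). In that setting 2 members passed as higher and 1 as lower over the list alone, against 12 lower without SU5402 replicate 2 (list median -1.07), 1 without DMSO replicate 2 and 2 without DMSO replicate 1. It was 1 with a pseudocount of 1, median centring, loess or the floor at the Tag background, and 0 with the floor and all probe sets kept. On average vcanb and fbln1 lay below the Tag background in the SU5402 arrays, as did prrx1b and barx1. Of 18 neural crest and cartilage genes, 12 were lower (median -0.71, interval -1.99 to 0.09). The mesenchymal homeobox genes prrx1b and prrx1a fell by 4.42 and 2.48 (SE 0.45 and 0.38), and the skeletal regulator gene runx2a, the cartilage matrix gene matn4 and barx1 were at -3.26 (SE 0.67), -2.06 (SE 0.44) and -2.46 (SE 0.61). These 5 passed limma over the list alone, and without DMSO replicate 1 barx1 was at -1.60. A second probe set of runx2a was at -0.16. Of the 6 genes that were higher, the cartilage gene cnmd and the neural crest gene foxd3 were at 1.42 (SE 0.51) and 1.29 (SE 0.49) without overlap between the groups, and did not pass over the list alone in limma (adjusted p = 0.0847 and 0.0864). Without DMSO replicate 2 cnmd was at 0.71, and foxd3 was at 0.63 without SU5402 replicate 1 and 1.96 without SU5402 replicate 2. The list passed limma camera at an adjusted p of 0.0122 (adjusted p = 0.657 with an estimated correlation). With values raised to the Tag background and all probe sets kept, the call was lost (limma camera, -0.59, adjusted p = 0.118) and 0 members passed over the list alone.

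Markers of other tissue also differed. Of 18 neuron and glia genes, 17 were higher after SU5402 (median 1.00, interval 0.48 to 1.19). The synaptic genes snap25a and cplx2a rose by 1.82 and 1.70 (SE 0.36 and 0.41) and the neuronal RNA binding protein gene elavl4 by 1.67 (SE 0.37), the 3 that passed limma over the list alone. The list passed limma camera (adjusted p = 6.68e-07, and adjusted p = 0.663 with an estimated correlation). Relative to each gene's mean, its median was -0.37 and -0.57 in the DMSO arrays, 1.02 in SU5402 replicate 1 and -0.05 in SU5402 replicate 2. Without SU5402 replicate 1 the list median was 0.42, and 0 members passed over the list alone. None passed without either DMSO array either, and 15 did without SU5402 replicate 2. With a pseudocount of 1 or either form of the floor, 0 passed. Of 20 epidermis and periderm genes, 19 were lower (median -0.53, interval -1.12 to -0.30), anxa1b fell by 3.38 (SE 0.55), the 1 member that passed limma over the list alone, and the keratin genes krt97 and krt17 were at -2.26 (SE 1.02) and -1.67 (SE 0.54). The list passed limma camera at an adjusted p of 0.0144 (adjusted p = 0.729 with an estimated correlation). This call rests on SU5402 replicate 1, where the list median was -1.33 against 0.74 in SU5402 replicate 2, and without it the list was at 0.20 (limma camera, adjusted p = 0.277). Without SU5402 replicate 2, 16 epidermal genes passed over the list alone, and without DMSO replicate 2, 0 did, nor did any with a pseudocount of 1 or either form of the floor. Both forms of the floor also ended the list's call (limma camera, adjusted p = 0.0694 with all probe sets kept and 0.0963 in the second form). Without SU5402 replicate 1, krt97 was at -0.59 and krt17 at -0.91. The ratio of the 3' to the 5' GAPDH control probe set, a sign of RNA quality, was 20.3 and 21.7 in the DMSO arrays and 26.6 and 29.7 in the SU5402 arrays. The ratio of the 3' to the middle GAPDH probe set did not separate the groups, at 3.9 and 3.71 in the DMSO arrays and 3.93 and 3.64 in the SU5402 arrays. The 3' to 5' ratio was higher in both SU5402 arrays than in both DMSO arrays. On all 4 arrays the 3' probe set read at least 20.3 times the 5' one, so 5' signal was weak throughout. Whether RNA quality contributed to the list changes was not tested.

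**Figure D2:**
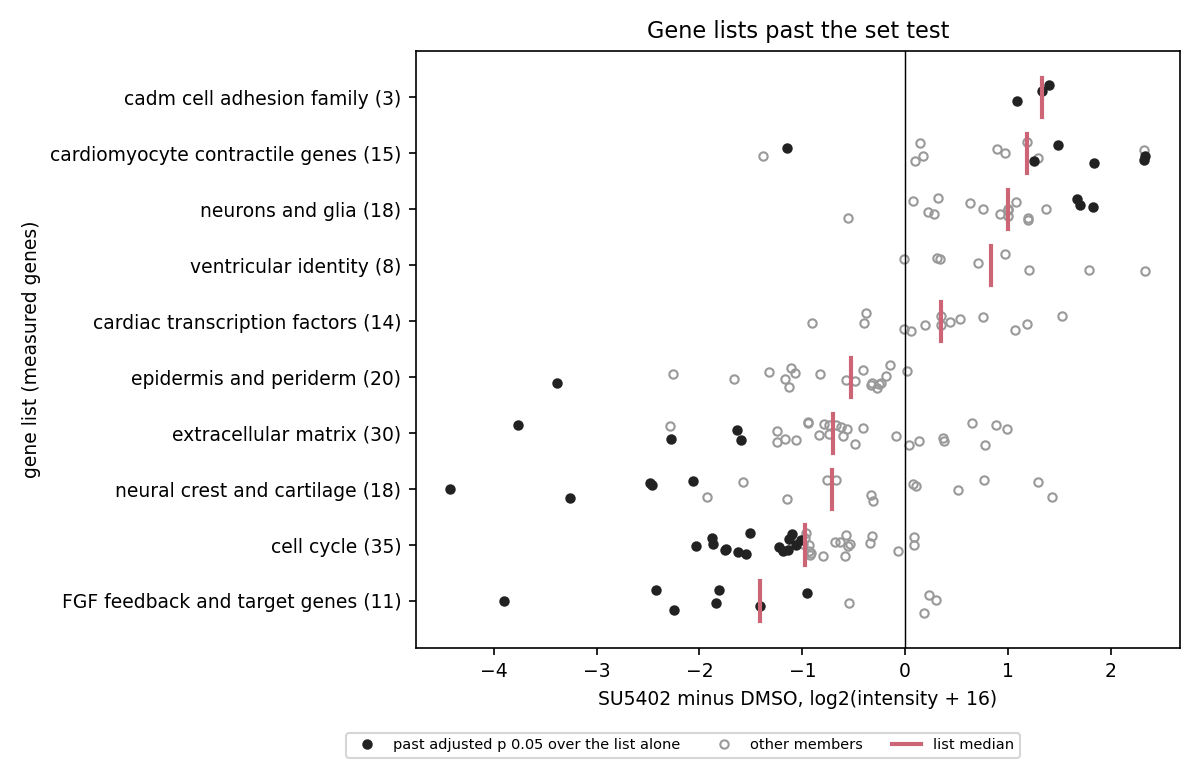
Change of each measured member (points, SU5402 minus DMSO on the log2(intensity + 16) scale) of the 10 gene lists past limma camera with its preset correlation, with the number of measured genes in brackets; filled points passed limma adjusted over the list alone, and vertical bars are list medians. Medians run from -1.41 for the FGF list to 1.33 for the Cadm family, and 0 of the 10 calls held with an estimated correlation. That form also found 0 of 20 simulated lists shifted by 1 log2 unit.

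**Figure D3:**
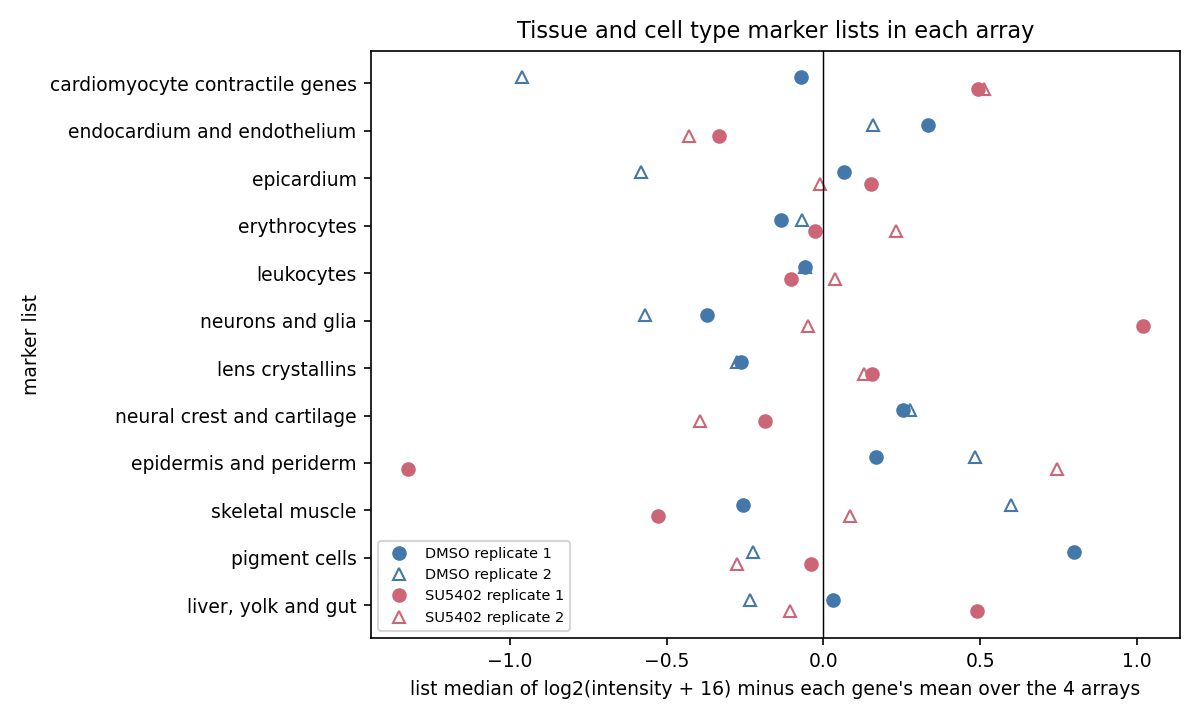
Median of each tissue or cell type list in each array, as log2(intensity + 16) minus each gene's mean over the 4 arrays; blue marks DMSO, red SU5402, circles replicate 1 and triangles replicate 2. The neuron and epidermis lists stand apart in SU5402 replicate 1, at 1.02 and -1.33.

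The other 19 lists did not pass limma camera, and their medians are given as values. The liver, yolk and gut list (adjusted p = 0.0526 in limma camera) passed without DMSO replicate 1, without SU5402 replicate 2 and with the mean of a gene's probe sets. Skeletal muscle passed without DMSO replicate 1 and without SU5402 replicate 2, atrial identity without the latter, pigment cells without DMSO replicate 2, leukocytes and the p53 list without SU5402 replicate 1, and immediate early genes without DMSO replicate 2 or without SU5402 replicate 1. Of the genes named next, myod1, pvalb2, sptb, tyr, mitfa and tbx18 lay on average below the Tag background in both groups, plvapb, myog, hey1 and vcanb in the SU5402 arrays, and crygs1 and fga in the DMSO arrays. With SU5402 replicate 1 left out, tfa, fga and aqp8a.1 were at 0.54, 0.67 and 0.75, and tspo at 0.10. Without DMSO replicate 2, tyr, podxl, tbx18, sptb and fga were at -0.21, 0.30, -0.28, 0.78 and 0.71, without DMSO replicate 1 mitfa was at -0.07, and without SU5402 replicate 2 crygs1 was at 1. Endocardium and endothelium genes had a median of -0.48 over 10 genes (adjusted p = 0.0819 in limma camera), with 2 of them lower over the list alone, the caveolar diaphragm gene plvapb and the ETS gene fli1 (both -1.86, SE 0.31 and 0.33), while kdrl was at -1.11 and aqp8a.1 at 1.46. A second probe set of fli1 was at 0.88. Skeletal muscle genes had a median of -0.40, with the muscle determination genes myod1 and myog at -1.58 and -1.60 and pvalb2 at 1.28. Lens crystallins were at 0.24 (crygs1 1.81, cryaa 0.71), liver, yolk and gut genes at 0.49 (tfa 1.99, fga 1.31), erythrocyte genes at 0.13 (sptb 1.3, tspo -1.06), pigment cell genes at -0.45 (tyr -0.66, mitfa -0.58) and epicardial genes at 0.42 (podxl 0.73, tbx18 -1.39). The crystallin genes cryba4 and crybb1 were bright in all 4 arrays, with DMSO means of 14.05 and 13.85. The heart muscle genes actc1a and myl7 had DMSO means of 12.57 and 10.36. The collections thus held strong lens signal, though signals of different probe sets need not compare in transcript number. Leukocyte genes had a median of -0.16 but a mean of 0.32, which mmp13a and mmp9 raised, and the test pointed up. Medians were -0.02 for FGF ligands and receptors, 0.08 for immediate early genes, 0.63 for atrial identity, 0.41 for p53 response and apoptosis, -0.25 for heat shock and unfolded protein response, -0.20 for BMP and TGF-beta response, and -0.05 for Wnt and Notch response, where 1 gene, hey1, was lower over the list alone (-1.74). Of the FGF ligands and receptors, 7 were higher and 7 lower, so their median hides changes both ways. Largest were fgf10a at -2.88 (SE 0.65), fgf13a at 1.38 (SE 0.36) and fgfrl1a at -1.32 (SE 0.36). Over that list alone 0 members passed limma. On average fgf10a, also in the outflow tract list, lay below the Tag background in the SU5402 arrays. In 4 other lists the median, mean and test differed in sign. Retinoic acid genes had a median of 0.13 and a mean of -0.42 with the test pointing down, and crabp2a and crabp2b (-1.72) were lower over the list alone. Outflow tract and second heart field genes had a median of -0.13 with the test pointing up, aryl hydrocarbon receptor genes a median of 0.19 and a mean of -0.17 with the test pointing up, and atrioventricular canal genes a median of 0.04 and a mean of -0.24 with the test pointing down and vcanb lower over the list alone.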

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

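Of the tests in this part, those of the FGF list after loess and over other splits had their predictions written before their results were seen, and all other tests were chosen after. The bound for differences between collections was also tightened after its values were seen, from 0.5 to 0.25 of the treatment difference, which moved the FGF list from excluded to open.

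Several control probe sets outside the comparison differed between the groups, with both SU5402 arrays above both DMSO arrays for those named in the next sentence. The 4 poly-A spikes, bacterial transcripts added to the RNA before labelling, were higher by 0.79 (dap), 0.89 (lys), 0.71 (phe) and 0.58 (thr) on the log2 scale, and the 3' GAPDH control probe set by 0.58. The 4 hybridization controls, added after labelling, differed by 0.10 to 0.22. Spikes exceeded hybridization controls by 0.60 on average and the ranges did not overlap, which argues against array brightness or scaling as the whole cause. All 4 of 4 spikes were higher in both SU5402 arrays, which is consistent with less sample RNA per unit of spike in those preparations, as a hypothesis found on the same data. Whether smaller collections or the treatment gave less RNA was not tested.

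The contractile and neuronal lists were higher, and the neural crest and cartilage list lower, in both SU5402 arrays than in both DMSO arrays. The epidermis list is left out of this pattern, since it was lower in SU5402 replicate 1 alone. A larger share of heart in otherwise alike tissue would lower all other tissue alike. The first test of this set neurons against epidermis (1.53), but without SU5402 replicate 1 it gave 0.22, so it was replaced, after that was seen, by neurons against neural crest and cartilage. These differed by 1.71, and by 1.26 (without SU5402 replicate 1) to 1.98 (without SU5402 replicate 2) with 1 array left out. In single arrays, the neuron median minus the crest and cartilage median was -0.63 and -0.84 in DMSO and 1.21 and 0.34 in SU5402, so replicates differed by up to 0.86. The lists moved apart by more than that, while a larger share of heart alone would lower both. The pair was picked after its directions were seen, so this gap describes these arrays and is no independent test of that explanation. A permutation of genes was run first and is not used, because genes of a list move together (estimated correlation 0.87 for neurons), and the bound from replicates was set after the values were seen. Cyclic loess left the contractile list at 1.23 (limma camera, adjusted p = 3.58e-04), which argues only against a trend with intensity of the kind loess removes. The correction was small, moving the median change over all probe sets by -0.006. Other biases tied to intensity were not tested. Tissue mix that varies between collections whatever the treatment stays open, since the DMSO arrays alone differed by 0.69 over the contractile list against a treatment difference of 1.19, and a response to FGF receptor block stays open with it, untested.

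The FGF target list was lower in the SU5402 arrays by a median of -1.41. After cyclic loess it was at -1.38 (limma camera, adjusted p = 3.35e-04), which argues only against a trend with intensity of the kind loess removes. That correction was small (-0.006 in the median change over all probe sets), and other biases tied to intensity were not tested. Tissue mix between collections stays open, because the DMSO arrays differed by up to 0.53 over this list. Of the 3 splits of the 4 arrays into pairs, 1, the real one, gave a median this large, and the highest other split gave 0.49, but 3 splits are too few for a share under 0.05. FGF receptor block, which the design names, stays among the open explanations, which the design cannot separate from a difference between collections. The 3' to 5' GAPDH ratio and the poly-A spikes also separated the groups. Whether RNA quality or amount contributed to the FGF or the contractile list was not tested.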

How the results depend on the processing

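The count of probe sets at an unadjusted p, the counts over a list alone across settings and both floors were chosen after the data were seen. The count past the adjusted threshold in limma was 0 in every setting except 2: it was 3 without SU5402 replicate 2 (0 to 3 over the arrays left out), where and2 and and3 passed at -6.72 and -6.9, and 21 with the first form of the floor, which kept 5602 probe sets at the floor on all arrays with no spread between replicates. Leaving those out gave 0, with 1618 at an unadjusted p under 0.05. The unadjusted count ran from 951 to 3011 with 1 array left out (955 without DMSO replicate 1). The FGF list median kept its sign in every setting and ran from -1.68 to -1.14 with 1 array left out; at -1.41, it did not pass camera with an estimated correlation (p = 0.236) or fry (p = 0.06). Lists called numbered 0 with an estimated correlation, 1 with fry, 7 with the first floor, and 9 to 13 otherwise, also with 1 array left out. Lists gained were liver, yolk and gut (replicate block, mean of probe sets), lens crystallins (dimmest 25% left out, second floor) and p53 response (dimmest 25% left out). The replicate numbers do not show shared clutches (2 pairs, replicate differences correlated at r = 0.28 across probe sets). With the replicate block the counts were 0 changed probe sets, 2582 at an unadjusted p under 0.05 and 11 lists, the FGF list had an adjusted p of 5.47e-04 in limma camera, and 9 and 2 contractile genes (higher and lower), 8 neuronal genes higher, and 2 and 8 crest and cartilage genes passed over their lists alone. With 1 array left out, signs turned for dct (-0.66 to 1.35) and wt1a (-0.36 to 1.19), lowest without DMSO replicate 2, dusp2 (-0.37 without DMSO replicate 1; -0.75 to 1.21) and tgm2b (0 to 1.39), lowest without SU5402 replicate 2, and dusp4 (-1.24 to 0.15), tspo (-2.23 to 0.10) and the epidermis list (-1.64 to 0.20), highest without SU5402 replicate 1; spry2 was at -0.23 as the mean of its probe sets. The other values of the 95 named genes kept their signs. The cardiac transcription factor list also lost its call with either floor (0.33 and 0.03) and without the dimmer 50% of probe sets (0.53), the epidermis list with either floor, and the crest and cartilage list with the first floor (-0.59). Counts over a list alone moved with the pseudocount: at 1, 6 FGF, 5 cell cycle, 0 contractile and 0 neuronal genes passed, and at 64, 7 FGF, 19 cell cycle and 7 neuronal genes but 0 higher and 1 lower contractile gene. Neuronal genes numbered 5 to 7 with trended variances or other normalisations, matrix genes 1 with median centring or loess. The first floor left 2 FGF, 1 cell cycle and 1 contractile gene (lower), and 0 neuronal, crest and cartilage, matrix or epidermal genes; the second left 1 matrix and 1 contractile gene (lower), and 0 neuronal or epidermal genes. Apart from the construction of the first floor, the cause of these changes was not tested. Signal over background limits what can be said of probe sets below the Tag level.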

Other observations

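The test of fin genes in this part had its prediction written before its result was seen, and the reporter values were looked up after the data were seen. The actinodin genes and1, and2 and and3 and the mesenchymal genes prrx1b and tbx15 differed from DMSO by -3.97 to -5.12 without passing the adjusted threshold of limma. Of the other fin genes, 4 Hox genes were lower at an unadjusted p under 0.05 in limma, but hoxa13b and hoxd9a lay on average below the Tag background in both groups, and hoxd11a and hoxa10b in the SU5402 arrays, so the sizes of their differences are not given weight here.

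A candidate explanation is that the SU5402 collections held less pectoral fin tissue. Over 24 fin genes not looked at before, 14 were lower and the median was -0.18 (95% bootstrap interval -0.91 to 0.26; limma camera, p = 0.279, and p = 0.353 with an estimated correlation). At an unadjusted p under 0.05 in limma, 4 of them were lower and 0 higher. Many of the 24, among them hoxd13a, hoxa9a, hoxa9b, hoxa11a and hoxa11b, lay on average below the Tag background in both groups. The list median is therefore a weak test of a loss of fin tissue. On average, the members above that background in both groups were emx2 (0.49), tbx3a (0.48), hoxb5a (0.38), shha (0.34), meis3 (0.31), dlx5a (-0.17) and dlx6a (-0.19). Whether the signal of these genes came from fin or from other tissue was not tested, so the list cannot decide the question. The interval covers both no change and a clear loss, so the data leave this open.

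The EGFP reporter control probe set read 35.8 and 36.9 in the DMSO arrays and 214.6 and 61.8 in the SU5402 arrays. The reading in SU5402 replicate 1 lay above the Tag background (136) and the other 3 below it.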
